A study of Mus musculus with 18 samples.

How the data were processed

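RNA was measured in 18 libraries, each made from 100 long-term haematopoietic stem cells (LT-HSCs) sorted from mouse bone marrow, in 3 groups of 6 mice: fresh cells at pH 7.4, cells cultured for 48 h at pH 7.4 and cells cultured for 48 h at pH 6.9. Per the labels' protocols, the medium held 10% fetal bovine serum with stem cell factor, G-CSF and thrombopoietin at 50 ng/ml, and the cultures were kept at 3% oxygen. The labels name the mice in one field as B6.SJL and in another as C57 B6 wild type. Libraries were made with SMART-Seq v4 Ultra Low Input and Nextera XT, which keep no strand information, and sequenced as paired ends of 75 bp. Each library carries a first index (i7) and a second index (i5). In every group the odd-numbered mice share 1 first index and the even-numbered mice another, so that each of the 6 sets of group and mouse parity has its own first index. Mice 1 and 2, 3 and 4, and 5 and 6 share a second index.

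Per the submitters' processing notes, reads were quantified with kallisto against mm10, without a version. The values deposited by the authors are expected or estimated counts per gene symbol, and every value is a whole number. How transcript estimates were summed to genes and rounded is not given in the sources used here. The table has 21003 gene symbols, of which 15842 had a count in at least 1 library, and all of its columns were matched to samples. Genes encoded by the mitochondrial genome were not analysed here. Because the libraries were amplified without molecular identifiers, floors and intervals from counts cover counting error only, and a count of 0 allows up to 3 counts of the library's total.

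Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), scaled by TMM and tested with robust quasi-likelihood fits that had 1 coefficient per group over all 18 libraries (10104 genes). Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05. Fold changes are log2 with their standard error (SE) from the fit, and counts scaled to CPM (counts per 1e+06) use the TMM-scaled totals. Gene lists were fixed before the data were examined. There were 50 lists with 1465 genes, written from general knowledge, and 1529 of 1566 entries matched a symbol, 3 of them by an older symbol. The 45 lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Counts "adjusted over the list alone" use the same edgeR p values adjusted within the list. Library measures (total count, genes detected, share of the 20 highest genes, ribosomal-protein and haemoglobin share) were compared between groups with exact two-sided permutation tests. Principal components used log2 CPM with a prior count of 2.

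The design text names 6 individual mice, so the replicate number was taken to pair libraries across groups. A fit with the mouse number as a term was run as an alternative, and pairing was checked by the correlation across genes of library profiles that share a number. To compare culture and pH effects, which share libraries, the shared group's libraries were split into 3 and 3 in all 20 ordered ways so that each effect used its own libraries, and the same slopes were computed on simulated counts without an effect. Of the comparisons, 3 between groups were planned. Fits with the 6 sets of group and mouse parity as coefficients, with tests within odd-numbered and within even-numbered mice and of the difference between them, were added after the libraries had been inspected. These fits use 15 libraries (10659 genes). They leave out the 3 libraries with a total under 1e+05 counts or fewer than 10000 genes detected, and the values with all 18 libraries are given as an alternative. Some of these sets hold 2 libraries, so that leaving out 1 of them leaves a lone library that is assumed to vary like the others.

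Genes are named by a rule written before the data were examined. It takes up to 8 genes per direction with the largest fold among those past the threshold that reach 10 CPM in a group and move the same way in 6 of 6 mouse numbers, or 5 of 6. Where fewer than 5 pass, it takes the 10 with the smallest unadjusted p. It adds up to 3 members of up to 8 called lists, and a fixed set of genes of polyamine metabolism, stem-cell identity, cell cycle and acid-base transport. The same rule was used within the odd-numbered and even-numbered mice. Coordinates are from GENCODE M21 on GRCm38 (mm10).

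Alternatives were DESeq2 size factors, no filter or a filter of 5 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with quality weights, a test against a 1.5-fold change, the mouse-number term, lists without shared members, and leaving out each replicate in turn. Those fits with simulated changes recovered 45.5% of genes set to a 4-fold change over 18 libraries, 0% at 2-fold and 2.99% at 1.5-fold, with 0 false calls. Within odd-numbered mice of the 15 libraries 51.5% were recovered at 4-fold and 16.4% at 2-fold with 3 false calls, and within even-numbered mice 66.7% and 26.9% with 1 false call. The test of the difference recovered 34.8% and 1.49% with 2 false calls. Numbers of splits with as many genes were counted over up to 100 splits of the libraries with a fixed seed of 20. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.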

Results

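Long-term haematopoietic stem cells (LT-HSCs), the rare bone-marrow cells that can renew all blood lineages, were profiled fresh or after 48 h of culture in medium at pH 7.4 or at pH 6.9. The series asks how the pH of the medium bears on the potential of these cells, with polyamine metabolism named in its title. Total counts ranged from 1640817 in pH 6.9 replicate 2 to 7508120 in pH 6.9 replicate 5, apart from fresh replicate 1, which held 6311 counts. The group means were 2862000 ± 1464000 (SD, n = 6) in fresh cells, 4513000 ± 2066000 at pH 7.4 and 3420000 ± 2338000 at pH 6.9. Fresh replicate 1 had 3035 genes detected, fresh replicate 4 had 9408 and pH 6.9 replicate 3 had 8925, against 11225 to 12792 in the other 15 libraries. Genes of cytosolic ribosomal proteins took 4.89% ± 1.10 of counts in fresh cells, 3.87% ± 0.589 at pH 7.4 and 4.43% ± 1.36 at pH 6.9 (SD, n = 6 each). In 15 exact two-sided permutation tests of library measures between groups, the smallest adjusted p was 0.551.

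The first principal component of all 18 libraries held 56.2% of the variance and set fresh replicate 1 apart. The second held 23.3%, with fresh replicate 4 at 193.75 and pH 6.9 replicate 3 at 184.32. Without these 3 libraries, the first component held 23.3% of the variance and followed the parity of the mouse number within each group. At pH 7.4 the odd-numbered mice scored 42.5, 31.97 and 30.04 and the even-numbered mice -1.67, -4.11 and -9.13. At pH 6.9 the order was opposite, with -64.89 and -52.7 in odd-numbered and 34.57, 41.96 and 43.75 in even-numbered mice. Fresh even-numbered mice scored -43.2 and -35.78 and fresh odd-numbered mice 1.68 and -14.99. In each group the odd-numbered and even-numbered mice carry different first indices, so the parity is also a set of libraries that the labels name. Each comparison below is given over all 6 mice and then within odd-numbered and even-numbered mice.

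**Figure D1:**
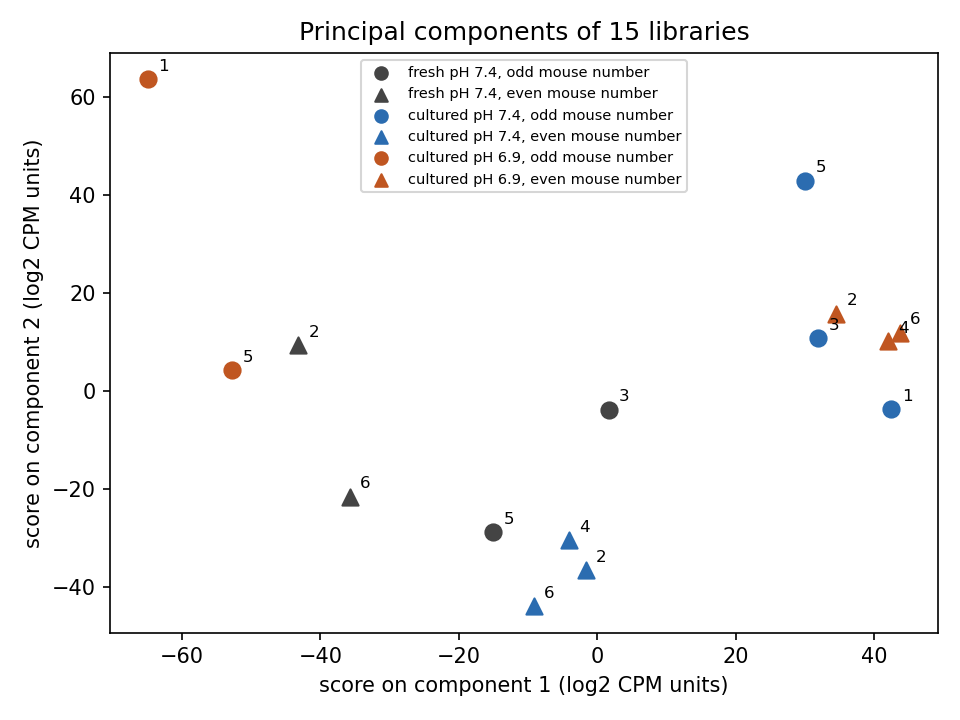
Scores of 15 libraries on the first and second principal components of log2 CPM, coloured by group and marked by the parity of the mouse number. The odd-numbered pH 7.4 and the even-numbered pH 6.9 libraries sit together at 30.04 to 43.75 on the first component.

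Between pH 6.9 and pH 7.4, the most separated genes over 6 mice were higher at pH 6.9, and none of the genes that make polyamines passed. Sprr2a1, a small proline-rich protein of epithelia, stood at 154 ± 206 CPM (SD, n = 6) at pH 6.9 against 0.243 ± 0.408 at pH 7.4 and was higher in 5 of 6 mouse numbers. Tm4sf1, a surface protein of the tetraspanin-like L6 family, stood at 95.7 ± 102 against 8.97 ± 3.38, and Uchl1, a ubiquitin hydrolase, at 21.8 ± 17.5 against 3.05 ± 1.81, both higher in 6 of 6. Procr, the protein C receptor used to sort stem cells, was 29.1 ± 15.3 against 12.9 ± 5.61 CPM and higher in 6 of 6, with a log2 fold change of 1.17 ± 0.54 (SE) and an edgeR p of 0.0422 before adjustment. None of these passed edgeR's quasi-likelihood test, with adjusted p = 0.267 for Sprr2a1, 0.557 for Tm4sf1, 0.561 for Uchl1 and 0.997 for Procr. Slc16a1, a lactate and proton transporter, was lower in 5 of 6 mouse numbers, at 79.3 ± 37.3 against 165 ± 80.5 CPM (log2 fold change -1.05 ± 0.45, adjusted p = 0.997). Mpo, the myeloperoxidase of granule-forming progenitors, was 19.9 ± 30.3 against 874 ± 1220 CPM, with a spread larger than its mean. Over the 15 libraries the high values at pH 7.4 were all in even-numbered mice. There Mpo was 1100, 1040 and 3200 CPM at pH 7.4 and 1.17, 9.97 and 6.63 at pH 6.9. In odd-numbered mice it was 8.21, 4.12 and 4.02 CPM at pH 7.4 and 21.1 and 0.975 at pH 6.9.

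Odc1 (chromosome 12, 17544794 to 17551505, plus strand of mm10) encodes ornithine decarboxylase, the entry enzyme of polyamine synthesis, and stood at 415 ± 164 CPM at pH 6.9 and 385 ± 67.1 at pH 7.4. Srm (chromosome 4, 148591503 to 148594993, plus strand), spermidine synthase, stood at 473 ± 279 and 497 ± 246 CPM. Their log2 fold changes were 0.11 ± 0.28 and -0.07 ± 0.43 (SE, n = 6 each), each higher in 3 of 6 mouse numbers. Amd1 and Sms, which supply and use decarboxylated S-adenosylmethionine for spermidine and spermine, were 148 ± 76.9 against 194 ± 42.0 CPM and 49.1 ± 13.3 against 61.3 ± 18 (adjusted p of 0.997 each by edgeR). Eif5a, whose protein carries hypusine made from spermidine, had -0.31 ± 0.51. Of 13 genes of polyamine synthesis, 0 passed edgeR over all genes or adjusted over the list alone, and 4 had a positive fold change, with a median of -0.32. That list was not called by camera (adjusted p = 0.244, and 0.728 with an estimated correlation), nor were the 12 genes of polyamine breakdown, antizymes and transport (0.246 and 0.728), of which 1 passed adjusted over the list alone. The 4 genes of eIF5A hypusination had an adjusted p of 0.066 and the 5 proton-sensing receptors and channels 0.519.

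Relative to other genes, 14 of 45 lists were called between pH 6.9 and pH 7.4, 8 up and 6 down, by camera with its preset correlation, and none with an estimated correlation (smallest adjusted p = 0.406) or by fry. The up lists were led by cytosolic ribosomal proteins, with 75 of 78 fold changes positive and a median of 0.35 (adjusted p = 3.13e-08), and oxidative phosphorylation, with 68 of 75 positive and a median of 0.44 (3.5e-08). Proteasome genes had a median of 0.59 with 28 of 35 positive (0.000531), mitochondrial ribosomal proteins 0.44 with 52 of 64 (0.000214), and LT-HSC identity genes 0.24 with 26 of 43 (0.0334). Interferon response genes were up with 30 of 41 positive (0.000343), as were the lists of MHC class II, with 5 of 9 positive and a median of 0.29 (0.0247), and of monocytes and macrophages, with 7 of 7 (0.00589). Of these MHC and monocyte genes, 4 and 2 passed adjusted over the list alone, and 0 in the other called lists. The monocyte gene Lyz2 was 479 CPM in pH 6.9 replicate 3, against a mean of 164 in the 15 libraries. G2/M and mitosis genes were down with 12 of 56 positive and a median of -0.39 (2.72e-06), and granulocyte-monocyte progenitor genes with 3 of 24 positive and -0.61 (0.000335). ATF4 targets had 7 of 39 positive (0.00208), glycolysis 9 of 31 (0.0197), acid-base transport 4 of 19 (0.0326) and fatty acid synthesis 3 of 15 (0.0174). No list was called with an estimated correlation, where the interferon list had adjusted p = 0.406, the MHC class II and monocyte lists 0.43 and the others 0.728, nor by fry (smallest adjusted p = 0.483). Without mouse number 1, 9 lists were called. For single genes, edgeR called 0 of 10104 over 6 mice, with 254 at an unadjusted p under 0.05. DESeq2 called Sprr2a1, Tm4sf1, Plscr2 and Uchl1, all up, and limma-voom called 0, with 1716 at an unadjusted p under 0.05.

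Odd-numbered and even-numbered mice were then taken apart. The polyamine enzymes Srm and Odc1, the translation factor Eif5a and the arrest gene Cdkn1a differed between pH 6.9 and pH 7.4, in opposite directions in the different sets of mice. Within each set of mice the first index differs along with pH, so these tests cannot separate pH from the index. In odd-numbered mice (2 libraries at pH 6.9 against 3 at pH 7.4), Srm rose from 284 ± 26.7 to 754 ± 34.0 CPM (SD), Odc1 from 331 ± 32.7 to 584 ± 84.2 and Eif5a from 2300 ± 154 to 4460 ± 299. In even-numbered mice (3 against 3), Srm fell from 730 ± 97.5 to 224 ± 54.4 CPM, Odc1 from 452 ± 9.80 to 274 ± 26.5 and Eif5a from 4120 ± 187 to 2080 ± 307. The log2 fold changes of Srm were 1.41 ± 0.24 (SE, edgeR adjusted p = 0.00161) and -1.71 ± 0.22 (0.000495), and their difference had an adjusted p of 1.55e-05. Those of Odc1 were 0.82 ± 0.17 (0.00709) and -0.72 ± 0.16 (0.011), with 0.000232 for the difference, and those of Eif5a 0.96 ± 0.18 (0.00314) and -0.98 ± 0.16 (0.00208), with 3.52e-05. For Odc1, the call in odd-numbered mice was lost without pH 6.9 replicate 5 (adjusted p = 0.0775), and that in even-numbered mice without pH 7.4 replicate 6 (0.0757) or pH 6.9 replicate 2 (0.0505). Cdkn1a (chromosome 17, 29090976 to 29100727, plus strand), the p53 target p21 that halts the cell cycle, went the other way. It fell to 95.8 ± 20.1 from 281 ± 106 CPM in odd-numbered mice (-1.57 ± 0.30, adjusted p = 0.00386, but 0.0513 without pH 6.9 replicate 5) and rose to 264 ± 35.7 from 66.0 ± 10.0 in even-numbered mice (2.00 ± 0.26, 0.000495). In all of these genes the libraries of the groups compared did not overlap. With all 18 libraries none of these calls was kept (for Srm, adjusted p = 0.0957 and 0.195). In even-numbered mice the libraries compared are the same in both fits, and the log2 fold change of Srm was -1.69 with all 18. In the even-numbered mice of the 15 libraries, granule genes were lower at pH 6.9 as well. There Ctsg was 189, 133 and 597 CPM at pH 7.4 and 0, 0 and 0.195 at pH 6.9, and Elane 18.2, 35.5 and 218 against 0, 2.42 and 0.195. In odd-numbered mice Ctsg was 0, 2.27 and 0.402 CPM at pH 7.4 and 3.73 and 8.49 at pH 6.9, and Elane 0, 0 and 0 against 0.622 and 0.

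Other genes passed in 1 set of mice in the fit of 15 libraries with its filter. In even-numbered mice Slc16a1 fell to 62.2 ± 6.96 from 236 ± 27.8 CPM (n = 3 each, edgeR adjusted p = 0.000883), and Txnip, an arrestin-like inhibitor of thioredoxin and glucose uptake, rose to 172 ± 28.7 from 60.3 ± 19.2 (0.00339). Smox, spermine oxidase, rose to 31.9 ± 10.6 from 8.55 ± 2.03 CPM (0.00647, but 0.0539 without pH 7.4 replicate 6). Sat1, which acetylates spermidine and spermine for breakdown or export, rose to 205 ± 37.0 from 96.6 ± 11.5 CPM (adjusted p = 0.0309). Sat1 lost its call without pH 7.4 replicates 2 (0.118), 4 (0.066) or 6 (0.0932), without pH 6.9 replicates 2 (0.0848) or 6 (0.13), and with the mouse number in the fit (0.0569). In odd-numbered mice these had adjusted p of 0.544, 0.0723 (0.0462 without pH 7.4 replicate 5), 0.759 and 0.144. The differences between the sets of mice had 0.000908, 0.000703, 0.0128 and 0.0067. Without a filter Txnip and Sat1 fell in odd-numbered mice (log2 fold changes -0.89 and -0.75, adjusted p = 0.0248 and 0.0471), opposite to even-numbered mice. Ccnb2 and Cenpa, needed for mitosis and chromosome segregation, fell in odd-numbered mice to 33.8 ± 24.9 from 401 ± 49.3 CPM (8.09e-05) and to 25.0 ± 23.9 from 187 ± 22.8 (0.000782). In even-numbered mice they had adjusted p of 0.607 and 0.123. None of these calls was kept with all 18 libraries (0.102 for Ccnb2 and 0.611 for Slc16a1).

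**Figure D2:**
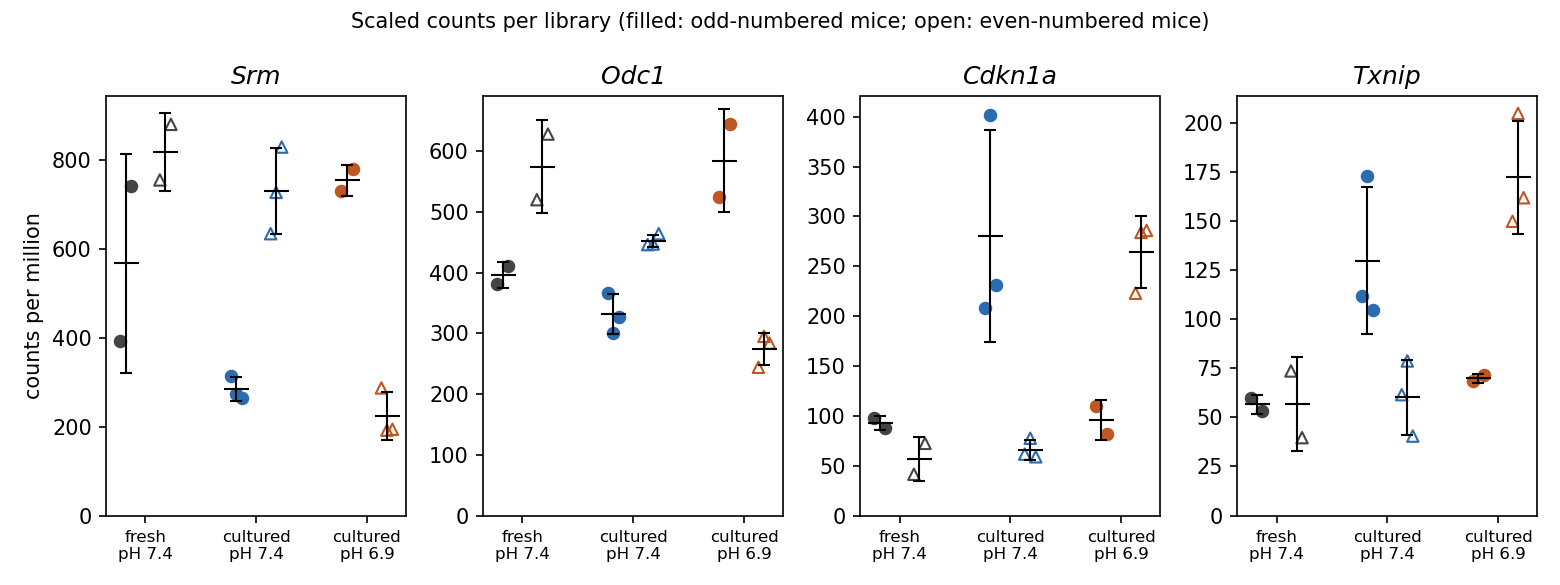
CPM of Srm, Odc1, Cdkn1a and Txnip in each of 15 libraries, by group and parity of the mouse number (filled, odd; open, even), with bars for the mean ± SD. Srm is 754 CPM on average at pH 6.9 and 284 at pH 7.4 in odd-numbered mice, against 224 and 730 in even-numbered mice.

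The lists for making and degrading proteins were called in opposite directions in the different sets of mice by camera with its preset correlation, though none with an estimated one. In odd-numbered mice 10 lists were called, 7 up and 3 down, and in even-numbered mice 28, 10 up and 18 down. Of 60 genes of ribosome biogenesis and MYC targets, 22 rose and 0 fell in odd-numbered mice (33 adjusted over the list alone, camera adjusted p = 4.71e-15), and 0 rose and 34 fell in even-numbered mice (47, 2.84e-31). For 78 cytosolic ribosomal proteins the counts were 33 up in odd-numbered mice (47 adjusted over the list alone, 2.6e-21) and 7 down in even-numbered mice (13, 2.62e-07). Proteasome genes gave 17 of 35 up (26 adjusted over the list alone, 1.02e-12) and 8 down (23, 1.35e-10). Polyamine synthesis had 3 of 13 genes up in odd-numbered mice (5 adjusted over the list alone, not called at 0.144) and 2 down in even-numbered mice (3, called at 6.41e-05). Lysosome and autophagy genes, which degrade and recycle cell components, had 10 of 59 down (10 adjusted over the list alone, 0.000413) and then 8 up and 1 down (13, 7.82e-05). G2/M and mitosis genes were down in odd-numbered mice, with 13 of 56 (24 adjusted over the list alone, 4.42e-12), and in even-numbered mice as well, with 1 (0 adjusted over the list alone, 0.00296). Quiescence genes were up in even-numbered mice, with 4 of 24 (8 adjusted over the list alone, 9.85e-06), and were not called in odd-numbered mice (3 down, 7 adjusted over the list alone, 0.0848). No list was called with an estimated correlation, with a smallest adjusted p of 0.41 in odd-numbered and 0.0767 in even-numbered mice, the latter shared by ribosome biogenesis, polyamine synthesis, quiescence and lysosome. By fry, which asks whether a list moves one way, 12 and 25 lists passed. The difference between the sets of mice had an adjusted p of 2.55e-29 for ribosome biogenesis, 0.00217 for polyamine synthesis and 1.4e-05 for lysosome (0.119, 0.17 and 0.119 with an estimated correlation). It was 3.05e-19 for cytosolic ribosomal proteins, 5.35e-21 for mitochondrial ribosomal proteins, 7.03e-16 for the proteasome, 2.88e-12 for oxidative phosphorylation, 0.000326 for quiescence and 0.00355 for G2/M (0.34, 0.235, 0.234, 0.343, 0.119 and 0.629 with an estimated correlation). Among the lists that did not differ were LT-HSC identity (0.258), glycolysis (0.307) and ATF4 targets (0.877).

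By edgeR, 1181 of 10659 genes passed for pH in odd-numbered mice (540 up, 641 down) and 719 in even-numbered mice (285 up, 434 down) over 15 libraries. The change differed between the sets of mice for 1924 genes. Of 305 genes that passed in both, 302 changed in opposite directions and 3 in the same one, against 79.7 in both if the sets were independent. Across genes, which are not independent replicates, the fold changes had r = -0.31. With the mouse number in the fit the counts were 775, 657 and 1628. With all 18 libraries edgeR called 65, 0 and 173, where the 0 stands beside 536 at an unadjusted p under 0.05, and DESeq2 and limma-voom, run over 15 libraries, called 1097 and 1724 in even-numbered mice. The odd-numbered count was 464 without pH 6.9 replicate 1, 578 without pH 6.9 replicate 5 and 656 without pH 7.4 replicate 1. The even-numbered count was 161, 340 and 420 without pH 7.4 replicates 6, 2 and 4, and 207 and 373 without pH 6.9 replicates 6 and 4.

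**Figure D3:**
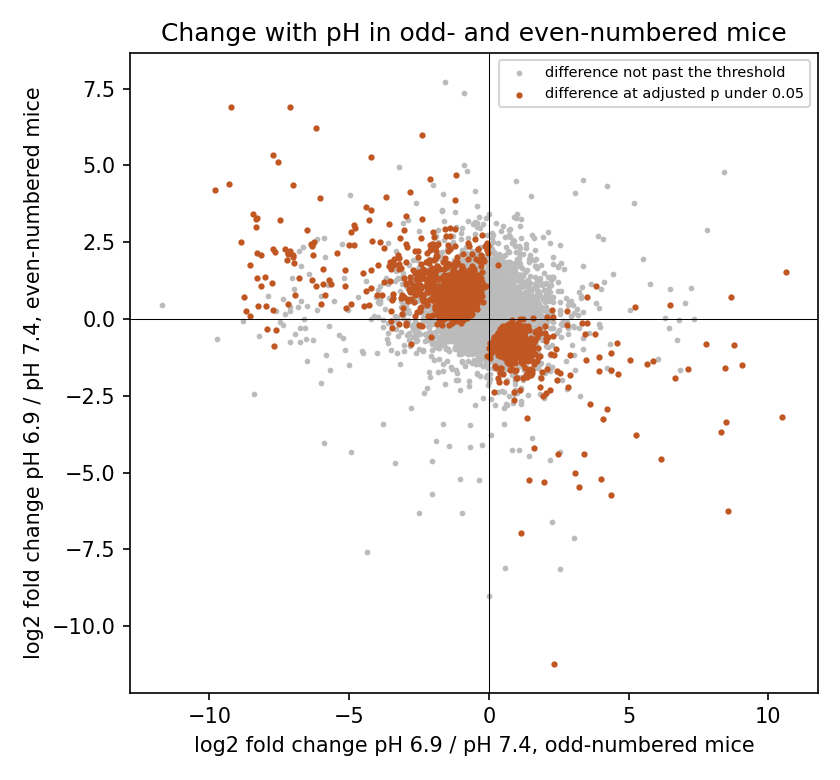
Log2 fold change between pH 6.9 and pH 7.4 in odd-numbered mice (x axis) and even-numbered mice (y axis) for 10659 genes over 15 libraries, coloured where the difference had an adjusted p under 0.05. The 1924 coloured genes lie mainly where the signs are opposite, and r across genes is -0.31.

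Culture at pH 7.4, against fresh cells, went with lower ribosomal and respiratory gene sets and higher lysosomal, p53 and megakaryocyte sets over 6 mice by camera with its preset correlation, while single genes did not pass. All of these list calls were lost with an estimated correlation (adjusted p = 0.739 each) and by fry. Itgb5, an integrin chain, was 26.6 ± 27.5 CPM (SD, n = 6) after culture against 0.970 ± 1.41 in fresh cells and higher in 6 of 6 mouse numbers (log2 fold change 4.35 ± 1.31). The MHC class II genes H2-Aa and Cd74, which present antigen, were lower at 0.602 ± 0.730 against 15.3 ± 19.2 CPM and 3.75 ± 3.29 against 41.1 ± 49.1, and not higher in 5 of 6 and 4 of 6 mouse numbers. The highest fresh value of H2-Aa, 49.5 CPM, was in fresh replicate 4, against a median of 1.43 in the 15 libraries. Cdkn1a was 171 ± 134 against 77.3 ± 57.0 CPM and higher in 4 of 6, and Txnip 93.6 ± 46.0 against 38.9 ± 28.5 and higher in 5 of 6. The direction in mouse 1 rests on the 6311 counts of fresh replicate 1, too few to measure genes at these levels. All of these had an edgeR adjusted p of 0.879. EdgeR called 0 genes, with 381 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well, with 405 and 1107.

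Camera called 10 of 45 lists between pH 7.4 and fresh cells, 5 up and 5 down. Down were cytosolic ribosomal proteins, with 1 of 78 fold changes positive and a median of -0.58 (adjusted p = 4.29e-21), oxidative phosphorylation with 4 of 75 and -0.66 (1.47e-20) and mitochondrial ribosomal proteins with 10 of 64 and -0.57 (2.14e-10). Proteasome genes (6 of 35 positive, 1.77e-06) and ribosome biogenesis (12 of 60, 0.000593) were down as well. Up were lysosome and autophagy genes with 46 of 58 positive (0.00118), p53 targets with 23 of 27 (0.0225), cytokine and STAT targets with 24 of 32 (0.0225), megakaryocyte and platelet genes with 26 of 29 (0.0377) and ATF4 targets with 32 of 39 (0.0377). With an estimated correlation all of these had adjusted p = 0.739, and by fry the smallest was 0.459. In these lists 0 genes passed over all genes or adjusted over the list alone. The 9 MHC class II genes were not called (0.145), though 6 passed adjusted over the list alone.

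Within parities, culture at pH 7.4 changed few genes in the filtered edgeR fit (12 and 11, but 317 and 369 without a filter), and progenitor and mitotic lists were called in opposite directions by camera with its preset correlation, but not with an estimated one (the difference had adjusted p = 0.444 for each). Wdfy1, an endosomal protein, rose in odd-numbered mice from 12.4 ± 1.89 (n = 2) to 156 ± 16.3 CPM (n = 3), with a log2 fold change of 3.65 ± 0.33 and an edgeR adjusted p of 1.01e-05. In even-numbered mice it had 0.44 ± 0.27 (0.534), and the difference had an adjusted p of 0.00229. S1pr1, the sphingosine phosphate receptor that guides blood cells, rose in odd-numbered mice from 20.9 ± 2.89 to 85.4 ± 18.8 CPM (0.0158), and lost its call without fresh replicates 3 (0.0546) or 5 (0.219) or pH 7.4 replicate 5 (0.0515), with the mouse number in the fit (0.0507) and by limma-voom (0.0814). With all 18 libraries Wdfy1 kept its call (0.00699) and S1pr1 did not (adjusted p of 1). The counts were 12 genes in odd-numbered mice (11 up, 1 down), 11 in even-numbered mice (6 up, 5 down) and 11 for the difference, with 1122, 1317 and 1066 at an unadjusted p under 0.05. With the mouse number in the fit they were 16, 5 and 12, and with all 18 libraries 1, 0 and 0, with 229, 963 and 427 at an unadjusted p under 0.05. DESeq2 called 173, 135 and 108 over 15 libraries, and limma-voom 2, 23 and 1. Granulocyte-monocyte progenitor genes were down in odd-numbered mice (median -1.66 over 26 genes, camera adjusted p = 0.00886, 0.646 with an estimated correlation) and up in even-numbered mice (1.62, 1.44e-09, 0.343). G2/M and mitosis genes had medians of -0.66 (1.73e-16, 0.524) and 0.54 (6.85e-06, 0.736). The difference had an adjusted p of 6.91e-11 for the progenitor list and 5.77e-22 for the mitotic list (0.444 each with an estimated correlation). The granule genes Mpo, Elane and Ctsg differed between the 2 fresh odd-numbered libraries. They stood at 4.02, 0 and 0.71 CPM in replicate 3 and at 3140, 315 and 728 in replicate 5. Mpo was 8.21, 4.12 and 4.02 CPM in odd-numbered mice at pH 7.4, so for such genes the fall rests on fresh replicate 5. Lysosome and autophagy genes were up in both sets of mice (0.00154 and 0.00594, but 0.52 and 0.343 with an estimated correlation).

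The small counts for culture at pH 7.4 shifted when single libraries were left out, including libraries outside the comparison. In odd-numbered mice the count was 24 without fresh replicate 3, 1 without fresh replicate 5, and 7, 24, 6 and 7 without pH 7.4 replicates 2, 3, 5 and 6. Libraries at pH 6.9, and for counts within a set of mice those of the other set, enter only through the shared spread, scaling, filter and tested genes. Without libraries at pH 6.9 the odd-numbered count was 19, 7 and 20 (replicates 1, 2 and 5). In even-numbered mice the count was 1, 21, 24 and 3 without fresh replicates 2, 3, 5 and 6. It was 5, 0, 7, 0 and 1 without pH 7.4 replicates 1, 2, 3, 4 and 6, and 17, 4 and 17 without pH 6.9 replicates 1, 2 and 5. The count for the difference was 1, 30, 0 and 6 without fresh replicates 2, 3, 5 and 6, then 3, 4, 1 and 1 without pH 7.4 replicates 1, 2, 5 and 6, and 6, 7 and 6 without pH 6.9 replicates 2, 4 and 6.

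Culture at pH 6.9, against fresh cells, went with a higher list of NRF2 and glutathione genes and a lower mitotic list over 6 mice by camera, again with no single gene past the threshold. Both list calls were lost with an estimated correlation (adjusted p = 0.604 each). Hmox1, haem oxygenase, and Nqo1, a quinone reductase, are classic targets of the redox sensor NRF2. Hmox1 was 409 ± 165 CPM (SD, n = 6) against 125 ± 21.5 in fresh cells and higher in 6 of 6 mouse numbers (log2 fold change 1.77 ± 0.50). Nqo1 was 374 ± 118 against 191 ± 34.4 and higher in 5 of 6. Of the genes that break down polyamines, Sat1 was 193 ± 71.9 against 98.7 ± 27.8 CPM and Smox 23.9 ± 12.2 against 9.92 ± 5.55, each higher in 5 of 6. Here too the direction in mouse 1 rests on the 6311 counts of fresh replicate 1. The edgeR p values before adjustment were 0.00188, 0.00704, 0.0179 and 0.044, and each adjusted p was 1. EdgeR called 0 genes, with 229 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, with 240 and 1476.

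Camera called 12 of 45 lists between pH 6.9 and fresh cells, 6 up and 6 down. G2/M and mitosis genes were down with 1 of 56 fold changes positive and a median of -0.51 (adjusted p = 1.76e-15, 0.604 with an estimated correlation). Polyamine synthesis was down with 2 of 13 positive and a median of -0.17 (0.0472, 0.753). Ribosome biogenesis had 2 of 60 positive (1.47e-06, 0.73), cytosolic ribosomal proteins 3 of 78 and oxidative phosphorylation 4 of 75 (5.66e-06 each, 0.878), and mitochondrial ribosomal proteins 12 of 64 (0.00282, 0.878). LT-HSC identity genes were up with 35 of 43 positive and a median of 0.39 (0.012, 0.843), p53 targets with 20 of 27 (0.00282, 0.753) and NRF2 and glutathione genes with 23 of 35 (0.00811, 0.604). Lysosome and autophagy had 45 of 58 positive (0.000917, 0.843), fatty acid oxidation 17 of 22 (0.02, 0.604) and interferon response 28 of 41 (0.025, 0.604). In these lists 0 genes passed over all genes or adjusted over the list alone, and by fry the smallest adjusted p was 0.557. Of 12 polyamine breakdown genes 5 had a positive fold change (median -0.21), 2 passed adjusted over the list alone and the list was not called (adjusted p = 0.828). Without mouse number 6, 1 list was called and without mouse number 4, 7, while the 15 libraries gave 19.

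Within parities, mitotic genes such as Ccnb2 fell at pH 6.9 in odd-numbered mice, and in even-numbered mice Srm fell and lysosomal genes such as Ctsd rose. In odd-numbered mice (2 libraries against 2) Ccnb2 fell to 33.8 ± 24.9 from 429 ± 132 CPM (SD, edgeR adjusted p = 0.000283), Cenpa to 25.0 ± 23.9 from 309 ± 43.1 (0.000896) and Nusap1, a spindle protein, to 44.3 ± 10.8 from 294 ± 86.2 (0.00204). In even-numbered mice (3 against 2) Ctsd, a lysosomal protease, rose to 2370 ± 373 from 503 ± 45.9 CPM (8.69e-05), Grn, the lysosomal progranulin, to 212 ± 18.3 from 69.2 ± 4.99 (0.000233) and Sqstm1, an autophagy receptor, to 533 ± 85.6 from 160 ± 29.8 (0.000533). Srm fell to 224 ± 54.4 from 817 ± 88.7 CPM in even-numbered mice (0.000225). Cd74 fell to 1.5 ± 1.58 from 86.1 ± 58.1 CPM in even-numbered mice (0.00585) and in odd-numbered mice stood at 93.2 ± 23.7 against 4.89 ± 4.90 (0.118). With all 18 libraries Srm, Sqstm1 and Cd74 kept their calls in even-numbered mice (0.0436, 0.028 and 0.0248), but Ctsd (0.121), Grn (0.127) and, in odd-numbered mice, Ccnb2 (0.431), Cenpa (0.192) and Nusap1 (0.49) did not. Of 56 G2/M and mitosis genes, 11 fell in odd-numbered mice (49 adjusted over the list alone, camera adjusted p = 1.52e-55, 0.29 with an estimated correlation). In even-numbered mice 55 of 78 cytosolic ribosomal proteins fell (67 adjusted over the list alone, 3.21e-36, 0.172), as did 41 of 60 ribosome biogenesis genes (50, 8.94e-30, 0.112). There 13 of 59 lysosome and autophagy genes rose (17 adjusted over the list alone, 1.2e-07), the only list called with an estimated correlation (0.0447). The difference between the sets of mice had an adjusted p of 1.24e-32 for cytosolic ribosomal proteins and 4.46e-19 for G2/M (0.246 each with an estimated correlation).

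The counts for culture at pH 6.9 were 64 genes in odd-numbered mice (7 up, 57 down), 1164 in even-numbered mice (508 up, 656 down) and 1358 for the difference. The odd-numbered count was 391 without a filter, 264 by DESeq2 and 17 by limma-voom. Of 25 that passed in both, 24 changed in opposite directions. With the mouse number in the fit they were 20, 941 and 939, and with all 18 libraries 1, 82 and 678. The odd-numbered count was 16 without fresh replicate 3, 14, 22, 31, 41 and 150 without pH 6.9 replicates 1, 2, 6, 4 and 5, and 21, 140 and 37 without pH 7.4 replicates 2, 5 and 6. The even-numbered count was 422 and 556 without fresh replicates 2 and 6, and 560 and 754 without pH 6.9 replicates 6 and 4. The difference was 480 without fresh replicate 3 and 686 without fresh replicate 2.

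Pairs of the 6 sets of group and parity were compared in the same fit to place each set among the others. Between even-numbered pH 6.9 and odd-numbered pH 7.4 libraries edgeR called 0 genes, the only tool run there, with 393 at an unadjusted p under 0.05. It called 5 genes between fresh even-numbered and odd-numbered pH 6.9 libraries (751 at an unadjusted p under 0.05) and 2 between even-numbered pH 7.4 and fresh odd-numbered libraries (293). Between parities of the same group it called 6 genes in fresh cells (816), 355 at pH 7.4 and 1532 at pH 6.9.

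**Figure D4:**
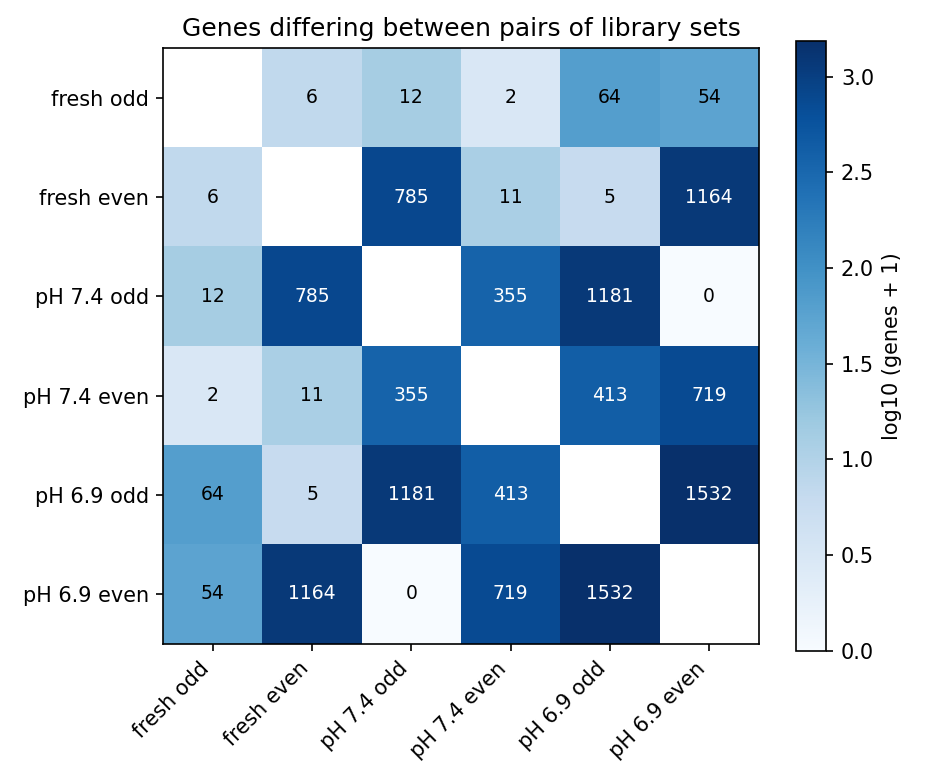
Number of genes past the edgeR threshold between each pair of the 6 sets of group and parity over 15 libraries, with the diagonal left empty. The lowest count, 0, is between even-numbered pH 6.9 and odd-numbered pH 7.4, and parities within pH 6.9 differ by 1532 genes.

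The culture responses at both pH values were compared across genes with separate fresh libraries behind each. The slope of the pH 6.9 response on the pH 7.4 response was 0.102 ± 0.206 (SD over 20 splits, -0.14 to 0.587), where simulated counts without an effect gave 0.0212 (0.00379 to 0.041). In counts simulated with a shared response of 0.5 or 1, the split slope was 0.328 and 0.654, so there it understates the share. Those culture changes were set to a log2 SD of 1, which was not matched to these data. The share in these data is therefore not settled. The covariance of both culture responses, from separate fresh libraries, was -0.00111 over 18 libraries and 0.0629 over the 15. With shared fresh libraries the slope was 0.478 against 0.538 in the simulation. Without mouse number 3 the split slope was 0.312, without mouse number 6 it was 0.0314, and over the 15 libraries it was 0.196 (0.0215 to 0.378). The covariance of the pH change with the culture change, from separate pH 7.4 libraries, was -0.135 ± 0.0484 (SD over splits, -0.184 to 0.0266). Simulated counts gave -0.0032 (-0.0132 to 0.0117). The simulations drew each gene independently, while genes in these libraries moved together. Their ranges are therefore too narrow to test the slope or the covariance. With shared libraries the covariance was -0.202, against -0.145 in the simulation. The split covariance was -0.0416 without mouse number 3, -0.0733 without mouse number 4, -0.212 without mouse number 6 and -0.0295 over the 15 libraries.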

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

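The tests within and between odd-numbered and even-numbered mice, including their splits, the matching of profiles and the tests of the 3 sparse libraries, were chosen after the results were seen, while those of depth, transcript length, GC content, other cell types and of splits over 6 mice were set out before them. Of 81 groups of 6 libraries tested for a library far from the others (Dixon's test), 16 had one, where chance gives about 1 in 20. Fresh replicate 1 stood out with a total of 6311 counts (others 2854046 to 3976777), 3035 genes detected (others 9408 to 12494) and -416.97 on the first component of all 18 libraries. Fresh replicate 4 had 14.08% of its counts in its 20 highest genes (others 7.43 to 9.12) and 193.75 on the second component. pH 6.9 replicate 3 had 8925 genes detected (others 11225 to 12516), 14.19% in its 20 highest genes (others 8.71 to 10.27), and scores of -105.9 and 184.32 on the first and second components (others 27.9 to 50.3 and -26.91 to 0.28). Haemoglobin genes took 0.0675% of counts in fresh replicate 2 (others up to 0.0242) and 0.00101% in pH 7.4 replicate 3 (others 0.0071 to 0.0107). Mpo was 3080 CPM in fresh replicate 5, 3130 in pH 7.4 replicate 6 and 79.8 in pH 6.9 replicate 3, against at most 962, 1080 and 21 in the other libraries of each group. Plscr2 was 619 CPM in fresh replicate 3 (others 44 to 259) and Sat1 318 in pH 7.4 replicate 5 (others 81.6 to 164).

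The change with pH differed between odd-numbered and even-numbered mice for 1924 of 10659 genes, by a test of the difference in the edgeR fit of 15 libraries. The change with culture differed for 11 genes at pH 7.4 and 1358 at pH 6.9. The genes below were named because they passed within a set of mice, some of them for the size of their fold or p in these same data. Their differences are therefore examples, and measure neither the usual size of the differences nor their number. Genes that build ribosomes and use or make polyamines had a higher log2 change with pH in odd-numbered mice: by 3.12 for Srm, 1.54 for Odc1, 1.94 for Eif5a, 2.47 for Nhp2, 2.76 for Npm1, 2.58 for Mrpl12, 1.66 for Rpl19, 1.71 for the chaperonin gene Tcp1 and 2.24 for Nme1. Slc16a1 differed by 2.25 in the same sense. In the opposite sense, Ccnb2 differed by -3.19, Cenpa by -1.95, Cdkn1a by -3.57, Txnip by -2.42, Sat1 by -1.85, Smox by -2.14 and the secreted protease Htra3 by -6.94. For culture at pH 7.4, Wdfy1 differed by 3.21 and Rgs12, a regulator of G-protein signals, by 3.05. For culture at pH 6.9 the mitotic genes Ccnb2, Cenpa and Nusap1 differed by -4.43, -3.81 and -3.44, and the lysosomal genes Ctsd, Grn and Sqstm1 by -2.85, -2.20 and -2.13. There Srm, Nhp2 and Rpl29 differed by 2.28, 2.42 and 2.00, Cd74 by 10.06 and the fatty acid carrier Fabp5 by 2.99. Of the lists, ribosome biogenesis differed for pH with a camera adjusted p of 2.55e-29, polyamine synthesis with 0.00217 and lysosome with 1.4e-05. G2/M and progenitor lists differed for culture at pH 7.4 with 5.77e-22 and 6.91e-11, and cytosolic ribosomal proteins and G2/M for culture at pH 6.9 with 1.24e-32 and 4.46e-19. With an estimated correlation none of these lists differed (adjusted p from 0.119 to 0.444).

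The opposed changes of odd-numbered and even-numbered mice form the first pattern. Of 100 assignments of the 15 libraries to the 6 sets, 1, the real one, gave as many genes that differed in any comparison (1726). The highest other was 941. Group and parity were shuffled at once, so these assignments do not test parity with the groups kept. With the groups kept, the mouse numbers can be parted into 3 and 3 in 10 ways. Of these 1, the real one, gave as many genes, but 10 are too few for a share under 0.05. The sets were also formed because the components had shown parity, a choice that the random assignments do not repeat. Chance is therefore not decided for the 6 sets or for parity alone. The 3 sparse libraries and depth are argued against as the whole cause, since 1924 genes differed without those libraries (173 with them) and 1804 after all libraries were thinned to 1640817 counts (median of draws with 1779 to 1808). A candidate explanation is that the group labels of 1 set of mice are rotated against those of the other: profiles matched across genes with r = 0.49 when odd-numbered fresh, pH 7.4 and pH 6.9 were set against even-numbered pH 7.4, pH 6.9 and fresh, with 0.13 for the next of 6 matchings, and 0.19 and 0.29 as the best matching of mice 1 and 2 and of mice 5 and 6, while for mice 3 and 4 most matchings rest on 1 pair of groups and decide nothing (rotation 0.07, highest 0.23 on 1 pair), and profiles centred over 3 groups fix in part that some matching is positive and another negative. The rotation cannot be told apart from mice that responded differently (r = -0.23 with the labels as given), nor from a difference that goes with the first index. Each set has its own index and nothing outside the expression values identifies it. Nor can the values tell which set of mice would carry the right labels.

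Fresh replicate 4 and pH 6.9 replicate 3 form the second pattern, as their deviations from the other libraries were correlated across genes (r = 0.72) though they belong to different groups and mice. Prmt1, an arginine methyltransferase, was 1350 and 1190 CPM in them against a median of 18.8 in the other 15, while Cdca4, Pef1 and Glb1 were at 0 in both against medians of 117, 87.1 and 84.5. In both, 27 genes above 20 CPM in each of the 15 were at 0, with 4.51 expected if all such genes were equally likely to be at 0. Genes of lower level are missed more easily, so 4.51 is a low expectation. GC content of transcripts may contribute, with Spearman's rho across genes of -0.34 and -0.37, both outside the -0.22 to 0.16 of the other libraries, while transcript length stays open, its rho of -0.23 and -0.25 (others -0.15 to 0.25) lying between the limits set beforehand. Cells of another type stay open: of 8 lists only that of monocytes and macrophages was higher in both (median log2 deviations 2.26 and 1.58 over 7 genes), with Lyz2 at 529 and 479 CPM against 164 and Cd68 at 220 and 207 against 66.3, yet Cd14 at 0 in both and Csf1r at 2.88 and 0 against 14.3. Both carry the second index 506, as do fresh replicate 3, pH 7.4 replicates 3 and 4 and pH 6.9 replicate 4, which scored -27.24, -24.8, -17.21 and -26.47 on the second component, and no group of the design holds both, so no biological difference that the design names was tested.

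The numbers of genes over 6 mice were also set against other splits of the libraries. With 0 genes in each comparison, 100 of 100 splits drawn from 462 gave as many, and the highest other counts were 1 for pH, 0 for culture at pH 7.4 and 607 for culture at pH 6.9. The split with 607 genes put fresh replicates 1, 2 and 4 with pH 6.9 replicates 1, 3 and 5, so that fresh even-numbered mice 2 and 4 stood with the odd-numbered mice at pH 6.9. It also puts all 3 sparse libraries on the same side, so it points to a structure of the samples in which parity and the sparse libraries are not separated. Within odd-numbered or even-numbered mice, 1 split, the real one, gave as many genes in each of 6 comparisons. There are 10 splits, or 3 for odd-numbered culture at pH 6.9, too few for a share under 0.05. The real counts there were 1181, 719, 12, 11, 64 and 1164, and the highest other was 184 for pH in odd-numbered mice and 0 in the rest.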

How the results depend on the processing

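Leaving out the 3 sparse libraries, the tests by parity and their alternatives were chosen after seeing the data, and the others before. Over 6 mice the counts of genes stayed at 0 in edgeR under every alternative run, and DESeq2 called 4 for pH. The called lists (14, 10 and 12) fell to 0, 0 and 0 with an estimated correlation and with fry, while the 15 libraries gave 19 for pH 6.9 against fresh cells. Without 1 mouse number they ranged from 9 to 16, 8 to 11 and 1 to 14. The slope of culture responses ranged from 0.0314 to 0.312 and the covariance of pH with culture from -0.212 to -0.0416, against -0.214 with differences within mouse number and -0.0295 over 15 libraries. In the fits by parity, counts are given for odd-numbered mice, even-numbered mice and the difference. All 18 libraries gave 65, 0 and 173 for pH, 1, 0 and 0 for culture at pH 7.4, and 1, 82 and 678 for culture at pH 6.9. Without a filter culture at pH 7.4 gave 317, 369 and 264 and culture at pH 6.9 in odd-numbered mice 391. DESeq2 gave 1097 for pH in even-numbered mice, 173, 135 and 108 for culture at pH 7.4 and 264 for culture at pH 6.9 in odd-numbered mice. limma-voom gave 1724, then 2, 23 and 1, and 17. The mouse number in the fit gave 775 for pH in odd-numbered mice, 5 for culture at pH 7.4 in even-numbered mice and 20 for culture at pH 6.9 in odd-numbered mice. In even-numbered mice the pH comparison holds the same libraries in the fits of 15 and 18. Its fall to 0 therefore comes through the spread, scaling, filter and tested genes that all libraries share. Which of these mattered was not tested, nor were the causes of the other shifts. Leaving out 1 library gave 464 to 1365, 161 to 910 and 1390 to 2017 for pH, 1 to 24, 0 to 24 and 0 to 30 for culture at pH 7.4, and 14 to 150, 422 to 1341 and 480 to 1559 for culture at pH 6.9. Lists by parity fell to 0 with an estimated correlation in 5 of the 6 comparisons and to 1 for culture at pH 6.9 in even-numbered mice. Fry gave 0 and 1 for culture at pH 7.4 and 2 for culture at pH 6.9 in odd-numbered mice, and all 18 libraries gave 9 for culture at pH 7.4 in odd-numbered mice. Of 4801 values of named genes over 6 mice, 4797 were called or uncalled as in the main fit and 4 gained a call. Of 4559 by parity, 3980 were called or uncalled as before, 563 lost a call and 15 gained one. Cd96 (culture at pH 7.4, even-numbered mice) reversed to -0.23 with all 18 libraries, the cause of which was not tested. A change of sign was counted only for genes with a call, so these numbers do not cover the direction of uncalled genes. Leaving out fresh replicate 1 alone, with its 6311 counts, gave 0 genes in each comparison over 6 mice in edgeR (281, 508 and 223 at an unadjusted p under 0.05).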

Other observations

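The matching of group profiles below was chosen after the opposed changes of odd-numbered and even-numbered mice had been seen. In odd-numbered mice at pH 6.9 and in fresh even-numbered mice, which differed by 5 genes in edgeR (751 at an unadjusted p under 0.05, where fresh libraries of different parity differed by 6 and 816), Srm stood at 754 ± 34.0 and 817 ± 88.7 CPM and Cd74 at 93.2 ± 23.7 and 86.1 ± 58.1 (SD, n = 2 each). In even-numbered mice at pH 6.9 and in odd-numbered mice at pH 7.4, which differed by 0 genes in edgeR (393 at an unadjusted p under 0.05), Cdkn1a stood at 264 ± 35.7 and 281 ± 106 CPM and Srm at 224 ± 54.4 and 284 ± 26.7 (n = 3 each). Genes of division were not tested as a list between these sets. In odd-numbered mice at pH 6.9 and fresh even-numbered mice, Mki67 stood at 119 ± 21.8 and 289 ± 109 CPM and Ccnb2 at 33.8 ± 24.9 and 194 ± 44.1 (n = 2 each). Mki67 was 214, 222 and 239 CPM in even-numbered mice at pH 6.9 and 234, 193 and 95.3 in odd-numbered mice at pH 7.4.

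Which pH went with higher Srm or higher Cdkn1a depends on the labels. If those of the odd-numbered mice hold, pH 6.9 may have raised genes of ribosome production with Srm and Odc1 and lowered mitotic transcripts, and if those of the even-numbered mice hold, it may have lowered the former and raised Cdkn1a and lysosomal genes. The profiles of both sets of mice matched with r = 0.49 under a rotation of labels and -0.23 as labelled, values that centring over 3 groups ties together. Hmox1 did not match between odd-numbered pH 6.9 (510 and 337 CPM) and fresh even-numbered libraries (104 and 110). It did match between even-numbered pH 6.9 (309, 626 and 520 CPM) and odd-numbered pH 7.4 (346, 618 and 427). With values both ways, a hypothesis of 1 response seen under different labels stays open beside that of opposed responses. A check of the index sheet against the culture records could show whether labels were rotated. New mice would not decide it, since the labels give no property of these mice beyond their number.

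Pairing by mouse number left little trace in the values. Profiles that share a number had a median correlation across genes of -0.02 over 18 pairs (-0.49 to 0.14), against 0.03 in 90 other pairs of libraries from different groups.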
